A study of Arabidopsis thaliana with 4 samples.

How the data were processed

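Arabidopsis thaliana plants, wild type and the hy5 mutant, had been kept for 4 days in white light without dark periods, per the labels. HY5 is a bZIP transcription factor that promotes light-dependent seedling development. Total RNA of both genotypes was labelled with Cy3 or Cy5 and hybridised to 4 two-colour arrays of long oligonucleotide probes, each array holding mutant and wild type together. The labels place the mutant in Cy3 on replicates 1 and 2 and in Cy5 on replicates 3 and 4, a balanced dye swap. The series' design text calls the 4 arrays biological replicates, and all 4 form 1 group.

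The only data used were the log2 ratios that the authors deposited, 1 value per probe and array. Per the submitters' processing notes limma was used, with no version, parameter or role given. Background correction, normalization within and between arrays, the spot filter that left cells empty, and the direction of the ratio are not given in the sources used here. The base of the logarithm is not stated either and was read as 2, as limma writes it. No intensities were used here, so dim or saturated spots could not be set apart and the number of arrays limits the precision. The column medians were 0.012, -0.0080, -0.0018 and -0.041 for replicates 1 to 4, and the median absolute deviations lay between 0.552 and 0.557, so the middle of the deposited columns was nearly equal in centre and spread. The tails were not, with SDs of 0.865, 1.11, 0.930 and 0.917.

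Of 27648 probes, 2032 were paired with 1 gene and 644 with several in the platform annotation supplied for this work, which can be old. The other 24972 probes are unnamed here. Symbols were updated through the Entrez ID in a gene table of the TAIR10.1 assembly, where 2029 of the 2032 probes matched. Probes of the same single gene were averaged on each array. Names were withheld from 26 genes (136 probes) for which 1 accession, typically a genomic clone, served 3 or more probes, a rule added after the annotation was seen, with the 3 genes spotted 17 times excepted. This left 1801 genes that could be named. No genomic coordinates are given because the sources name no build for the array. HY5 was not among the named genes and was not analysed here.

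The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided) on each feature's log ratio against 0, a feature being a gene or an unnamed probe with values on at least 3 arrays (24153 features). Benjamini-Hochberg adjusted p under 0.05 was the threshold. Ratios were also simulated with the real empty cells (24153 features, 10 runs of the comparison with the ratios as deposited). Noise was independent between arrays, with each feature's moderated variance, and over the runs 500 features were changed by each size. The same fit called 2.2% of features changed by 1 on the log2 scale, 62.4% of those changed by 2 and 88.8% of those changed by 3. It called 93.4% of those changed by 4 and 0.0351% of unchanged ones. These shares may not hold for the real arrays, where same-dye arrays were alike and the number of changed features is unknown. Gene lists with 3 or more members on all 4 arrays were tested with camera (preset correlation 0.01), with an estimated correlation, ranks and fry beside it, fry's mixed p being added after seeing the data. In simulated data camera gave p under 0.05 for 3.5% of unshifted lists of 4 and for 100% of lists shifted by 1. Noise there was independent between features and between arrays, and all members of a shifted list moved in the same direction. The 100% may therefore not hold for smaller or mixed changes or for the real arrays.

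The rule for the direction of the ratios was written before the data were examined. If arrays of opposite dyes correlated above 0, the table would be used as deposited, and if below 0, replicates 1 and 2 would be turned. The correlations came out on both sides of 0, a case the rule did not cover. Giving 2 readings side by side was decided after that outcome. By their mean, which was above 0, the ratios as deposited are the first reading. The second reading, planned as an alternative, multiplies replicates 1 and 2 by -1. Under the first reading the positive side is likely mutant over wild type, because the sample labels put the mutant first. Under the second, positive means mutant over wild type if the columns hold Cy5 over Cy3, as limma writes ratios, and the reverse if they hold Cy3 over Cy5.

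Gene lists (22 lists, 382 members), alternatives and the rule for named genes were fixed at the same stage as the direction rule. The rule took HY5, the 12 largest rises and 12 largest falls past the threshold or, with none past it, the 5 genes in each direction with the smallest p among genes with 4 values of 1 sign, and from each list up to 4 members past the threshold with the largest ratios or else the one with the smallest p. The rule was applied to both readings. All measured list members are named, which goes beyond it. Only 27 list members were tested, in 14 lists. No member had a named probe here, and none was analysed here, for the flavonoid regulators, the general phenylpropanoid and lignin enzymes, photoreceptors and light signalling, gibberellin and brassinosteroid, seed storage and maturation, or the stomatal and vascular markers. The alternatives tried were centring, scaling, a dye term, other rules for empty cells and for several probes, robust or no variance moderation, a fold threshold, each dye orientation alone, each array left out and the other sign. Symbol families of 10 or more genes were planned, and the largest held 8. Chosen after seeing the data were list tests on features with all 4 values, families of 7 or more genes, named genes as the background of the list tests, and a list of 73 class III peroxidase genes, written from general knowledge after 5 members had been seen.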

Results

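The comparison asked which transcripts differ between the hy5 mutant and wild type of Arabidopsis thaliana after 4 days in white light. It was made on 4 arrays, each a direct ratio of both genotypes. Replicates 1, 2, 3 and 4 held values for 25007, 26739, 25057 and 18004 of the 27648 probes. Replicate 4 therefore lacked 34.9% of its probes, against 3.29% to 9.55% on the others. The single-array spread of the ratios (SD) was 0.865, 1.11, 0.930 and 0.917 on the log2 scale.

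For 3 genes spotted 17 times per array, named for that reason, the spots with a value (13 to 17 per array) give the technical error within an array. AT2G17190 had mean log2 ratios of 0.042, 0.10, -0.031 and -0.12 on replicates 1 to 4, with SDs between spots of 0.150, 0.195, 0.517 and 0.441. TUA1, an alpha-tubulin gene, had means of 0.014, 0.12, 0.14 and -0.051, with SDs of 0.386, 0.163, 0.373 and 0.493. AT5G46430 was negative on every array, at -0.39, -0.30, -0.58 and -0.37, and its SDs between spots reached 1.19 on replicate 1 and 1.18 on replicate 3. Its medians over spots were -0.087, -0.30, -0.39 and -0.016. The medians of AT2G17190 were 0.018, 0.085, 0.079 and 0.042, opposite in sign to its means on replicates 3 and 4.

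Arrays labelled with the same dyes agreed more closely than arrays with swapped dyes. Across features, Pearson's r was 0.264 between replicates 1 and 2 and 0.229 between replicates 3 and 4. Between arrays of opposite dyes it was 0.038, 0.067, -0.049 and 0.080, with a mean of 0.034, and the mean Spearman rho was 0.0007. The mean share of features with equal signs was 48.91% for opposite dyes and 61.95% for the same dyes. The signs on opposite dyes thus leaned slightly to turning, unlike the mean of Pearson's r. Features are not independent replicates, so no p-value is attached. The deposited table therefore did not show whether the authors had already turned the dye-swapped arrays to 1 direction. If they had, a genotype difference keeps its sign on all 4 arrays, and if they had not, it turns its sign with the dyes. Both readings are given for the lists and their members, and no gene is called higher or lower in the mutant.

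Of 16577 features with all 4 values, 3177 (19.2%) had 1 sign on all 4 arrays and 3587 (21.6%) turned their sign with the dyes, where 4 independent signs would give 12.5% each. The agreement in sign within each dye orientation (66.4% and 60.1% of these features) would by itself give 19.9% each, so the 19.2% is no excess beyond it. The other 2 patterns that set 2 arrays against 2 held 8.45% and 5.91%. Ratios beyond 1 in size on every array were found for 107 features that kept their sign, 104 of them negative and 3 positive. Among the 50 such features that turned with the dyes, 30 were positive and 20 negative once replicates 1 and 2 were turned. With no relation between the dye orientations, the same-dye pairs would give 13.9 large negative and 1.01 large positive features of 1 sign, and 2.14 positive and 6.54 negative turning ones. All 4 counts found were higher. This reckoning gives every feature the same chance of a large ratio, so the excess cannot show a relation between the orientations.

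**Figure D1:**
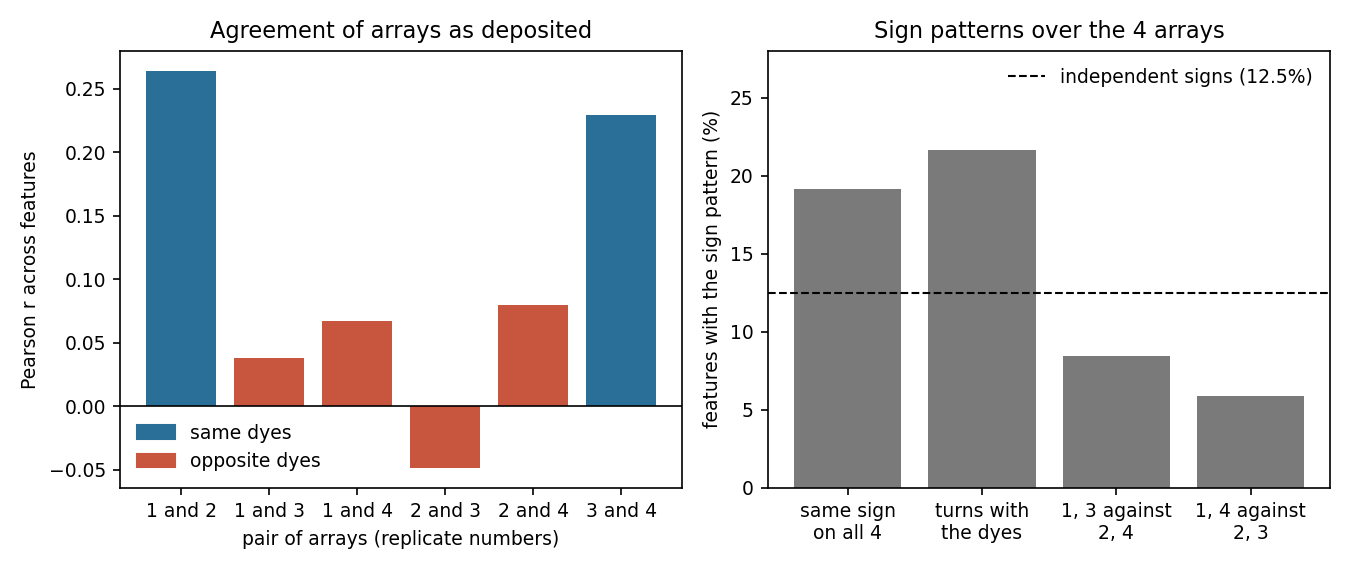
Left, Pearson's r between each pair of arrays across features, with the same dyes (blue) or opposite dyes (red). Right, the percentage of the 16577 features with 4 values that follow each sign pattern, with the share that 4 independent signs would give as a dashed line. Same-dye pairs reach 0.264 and 0.229, and opposite-dye pairs lie between -0.049 and 0.080.

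With the ratios as deposited, the 5 named genes of each sign with the smallest p had mean ratios between 0.64 and 1.48 or between -1.94 and -1.22. The tetrapyrrole enzyme gene hemf2 (AT4G03205, a coproporphyrinogen oxidase) had a log2 ratio of -1.94 ± 0.19 (SD, n = 4), a 3.83-fold difference. JAL33 (AT3G16450), a jacalin-related lectin, had -1.77 ± 0.56 (SD, n = 4), and JRG21 (AT3G55970), a jasmonate-regulated gene, had -1.52 ± 0.41 (SD, n = 4). RECQI1 (AT3G05740), a RecQ-type DNA helicase gene, had -1.34 ± 0.35 (SD, n = 4), and OBE1 (AT3G07780), encoding the PHD-finger protein OBERON1, had -1.22 ± 0.24 (SD, n = 4). On the positive side, AT5G66675 had 1.48 ± 0.36, AT4G19006 had 1.44 ± 0.88 and AT5G18940 had 1.02 ± 0.37 (SD, n = 4 each). AT1G80280 had 0.65 ± 0.14, and IVD (AT3G45300), the isovaleryl-CoA dehydrogenase of leucine breakdown, had 0.64 ± 0.17 (SD, n = 4 each). None of these passed the threshold. Their adjusted p in limma ran from 0.303 to 0.455. Under the other reading, all but AT4G19006 (-0.70) lay between -0.20 and 0.024.

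No feature of the 24153 tested passed an adjusted p of 0.05 in limma with the ratios as deposited, in either direction, and the smallest adjusted p was 0.303. At an unadjusted p under 0.05 there were 1829 features, 535 positive and 1294 negative. Independent arrays with no difference would give about 1208. Same-dye arrays were alike, which by itself raises the count, so the excess does not show a genotype difference. The ordinary one-sample statistic without variance moderation also gave 0 features after adjustment and 1752 before it. With 4 arrays the exact sign test of a single gene cannot go below a two-sided p of 0.125.

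With replicates 1 and 2 turned, the 5 named genes of each sign with the smallest p were other ones. LEA18 (AT2G35300), a late embryogenesis abundant protein gene, had a log2 ratio of 2.97 ± 0.75 (SD, n = 4), a 7.86-fold difference. AT1G04560, encoding an AWPM-19-like membrane protein, had 2.77 ± 1.12 (SD, n = 4), a 6.80-fold difference, and AT2G16005 had 2.16 ± 0.75 (SD, n = 4). The class III peroxidase genes AT5G64100 and AT3G01190 had 1.11 ± 0.19 and 1.03 ± 0.29 (SD, n = 4 each). Another peroxidase gene, AT3G49960, lay on the other side at -1.87 ± 0.52 (SD, n = 4), a 3.66-fold difference. Its 2 probes gave means of -1.76 and -1.99, and the 2 probes of AT3G01190 gave 0.89 over 4 arrays and 1.31 over 3 arrays. The AP2/ERF transcription factor gene tny (AT5G25810) had -1.71 ± 0.62 and AT1G76600 had -1.65 ± 0.70 (SD, n = 4 each). AT1G24530 had -1.16 ± 0.43 and AT3G07350 had -0.93 ± 0.30 (SD, n = 4 each). Again none passed the threshold, all 10 having an adjusted p of 0.465 in limma. As deposited, their means lay between -0.39 and 0.42.

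No feature passed the adjusted threshold in limma under this reading either, with a smallest adjusted p of 0.465, and the statistic without moderation gave 0 after adjustment and 2191 before it. At an unadjusted p under 0.05 there were 2122 features, 1079 positive and 1043 negative, against about 1208 for independent arrays with no difference. The likeness of same-dye arrays raises this count too. Without replicate 2 that count was 1316. In a model with a dye term, 0 features passed for the part that kept its sign and 0 for the part that turned with the dyes, against 2278 and 2578 at an unadjusted p under 0.05.

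**Figure D2:**
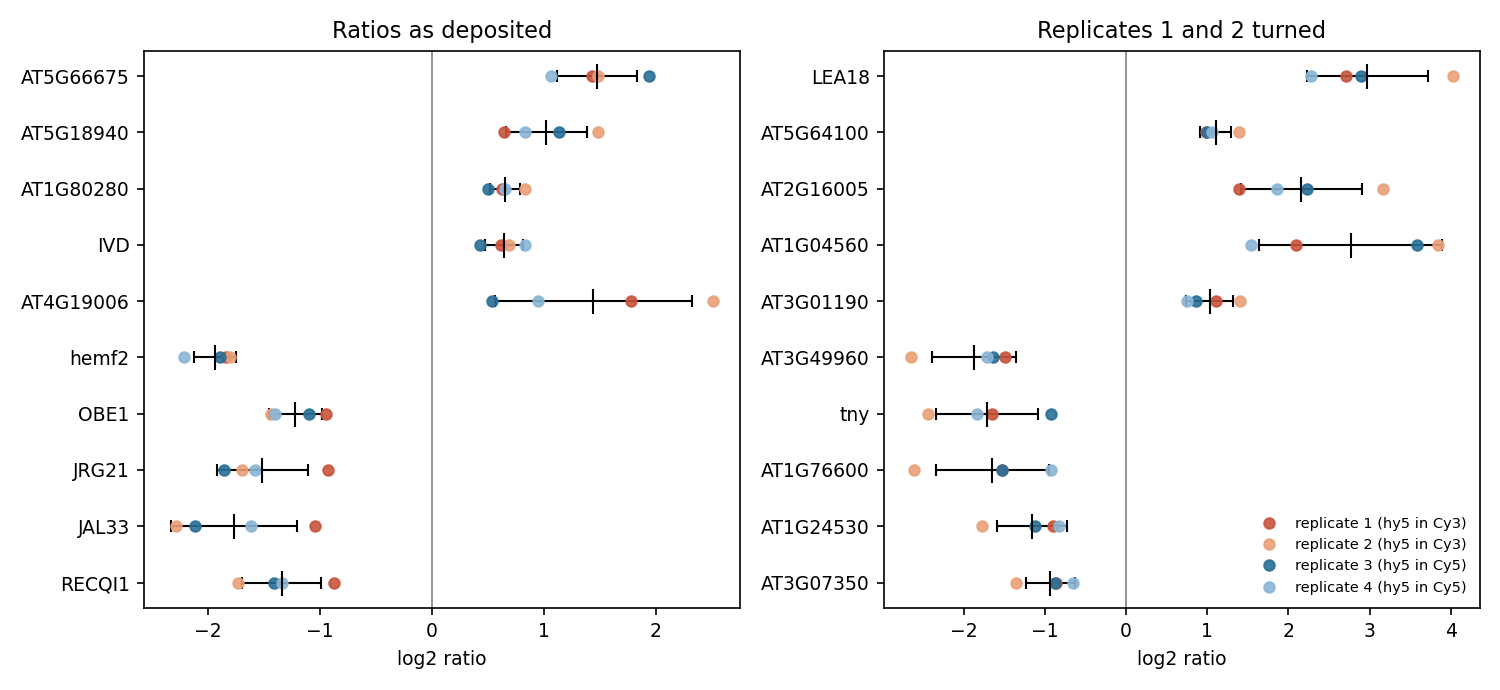
Log2 ratios of the 10 named genes of each reading on each array (points, coloured by replicate and by the dye of the mutant), with the mean (tick) and SD (bar). Left, ratios as deposited, from hemf2 at -1.94 to AT5G66675 at 1.48, and right, with replicates 1 and 2 multiplied by -1, from AT3G49960 at -1.87 to LEA18 at 2.97. The 4 arrays of each gene lie on 1 side of 0 by the selection rule, and no gene passed the adjusted threshold.

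All 4 named light-harvesting antenna genes failed the test of single genes under both readings. As deposited, LHB1B2 had 0.0050 ± 0.21, LHCB4.1 -0.048 ± 0.17, LHCB4.2 0.089 ± 0.45 and LHCB4.3 -0.14 ± 0.33 (SD, n = 4 each). Turned, they had 0.073 ± 0.19, -0.066 ± 0.16, -0.38 ± 0.12 and 0.19 ± 0.30, in the same order (SD, n = 4 each). The smallest adjusted p in limma was 0.552, for LHCB4.2 when turned. Antenna genes are close paralogs, and cross-hybridisation between them was not tested. Of 4 photosystem and carbon fixation genes, none passed. PSAE-1 had -0.29 ± 0.82, PSBY 0.11 ± 0.56, PSAN 0.045 ± 0.19 and ATPC1 0.035 ± 0.37 as deposited, and when turned they had -0.34 ± 0.79, -0.44 ± 0.28, -0.13 ± 0.13 and 0.015 ± 0.37, in the same order (SD, n = 4 each).

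The tetrapyrrole synthesis list was covered by 5 genes, of which 0 passed over all features. A further tetrapyrrole gene outside that list, hemf2, had -1.94 ± 0.19 (SD, n = 4) as deposited and -0.12 when turned. It was named for its small p as deposited and did not pass either. As deposited, HEMB1 had -0.35 ± 0.48, HEME2 -0.33 ± 0.32 and CHLM -0.087 ± 0.70 (SD, n = 4 each), and GSA1 had -0.044 ± 0.27 (SD, n = 3). Turned, they had 0.31 ± 0.52, -0.00028 ± 0.50, -0.35 ± 0.58 and 0.22 ± 0.076, in the same order and with the same n. PORB, the light-dependent protochlorophyllide reductase, had 0.0004 ± 0.95 as deposited and 0.78 ± 0.28 when turned (SD, n = 4). Its adjusted p in limma when turned was 0.465 over all features and 0.0323 adjusted over the list alone, the 1 call among the 5.

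Cold and abscisic acid response genes varied widely between arrays. COR47 had -0.29 ± 0.93, KIN1 0.17 ± 1.06 and KIN2 -0.45 ± 1.12 as deposited, and -0.64 ± 0.65, 0.55 ± 0.87 and 0.21 ± 1.21 when turned (SD, n = 4 each). KIN1 and KIN2 are near-identical neighbours, so their signals may not be separable. None of the 3 passed, over all features or adjusted over the list alone.

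These 4 lists were the only ones with at least 3 members on all 4 arrays, and none passed camera under either reading. The smallest adjusted p over the lists was 0.920 as deposited and 0.448 turned, and with an estimated correlation it was an adjusted p of 0.926 and 0.660. The directional fry test gave smallest adjusted p-values of 0.431 and 0.289, and no list passed it. Its mixed p, which asks for change in either direction and does not compare a list with other genes, passed for 2 lists when turned, with an adjusted p over the 4 lists of 0.0184 for the antenna genes and 0.0184 for tetrapyrrole synthesis. It was under 0.05 before adjustment for 24.1% of 1000 random sets of 4 named genes when turned and for 10% of 200 unshifted simulated lists. Without replicate 1, the adjusted p of both lists was 0.131. As deposited, 0 lists passed the mixed test, each with an adjusted p of 1. For the photosystem list as deposited, the median (0.040) and the test direction were positive while the mean (-0.024) was negative. For the antenna list when turned, the median (0.0034) was positive while the mean (-0.047) and the test were negative.

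The other lists with a named gene held 1 or 2 each, and none of those passed over all features under either reading. IAA29, an auxin-responsive repressor gene, had 0.36 ± 2.06 as deposited and -1.59 ± 0.79 turned (SD, n = 3). When turned, its adjusted p in limma was 0.484 over all features and 0.0128 over the list alone. The list held only this gene, so the latter equals the unadjusted p. THI2.1, a jasmonate-inducible thionin gene, had -0.77 ± 0.54 as deposited and 0.35 ± 0.96 turned (SD, n = 4). As deposited, its adjusted p in limma was 0.600 over all features and 0.0277 over the list alone, again of 1 gene. When turned, these were 0.803 and 0.423. No other single-gene list gave a call when adjusted over the list alone. UGT78D1, a flavonol glycosyltransferase gene, had 0.26 ± 0.25 and 0.21 ± 0.31, and EXPB3, a beta-expansin gene, had 0.12 ± 0.50 and -0.33 ± 0.35 (SD, n = 4; as deposited, then turned). The clock gene GI had -0.24 ± 0.43 and -0.23 ± 0.44, and the lycopene cyclase gene LYC had 0.071 ± 0.66 and 0.20 ± 0.62 (SD, n = 3, in the same order). The sulfite reductase gene SIR had -0.15 ± 0.29 and -0.16 ± 0.28, and the root-expressed beta-glucosidase gene PYK10 had 0.10 ± 0.20 and 0.096 ± 0.21 (SD, n = 4). The heat shock gene ATHSP22.0 had -0.26 ± 1.08 and -0.12 ± 1.12 (SD, n = 3). Of 2 reference genes, AT5G60390, an elongation factor 1-alpha gene, had 0.024 ± 0.034 and 0.024 ± 0.034 (SD, n = 4), and AT2G28390 had -0.17 ± 0.68 and -0.17 ± 0.68 (SD, n = 3).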

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

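PYK10 and KIN2 each had 1 array far from the other 3 by Dixon's gap test, in 3 of the 62 sets of 4 values tested. Chance flags about 1 set in 20. PYK10 was at 0.41 on replicate 4 and between -0.029 and 0.040 on the others as deposited, and the same array stood apart when replicates 1 and 2 were turned (0.41 against -0.040 to 0.029). KIN2 was at 1.99 on replicate 2 when turned, against -0.68 to -0.24 on the others.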

How the results depend on the processing

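The background of named genes alone and the mixed fry p for the list tests were chosen after seeing the data, and the other alternatives before. Each array already pairs mutant with wild type, so the test of the ratios against 0 uses that pairing, and with 1 group no further pairing was possible. Under every alternative run for features, 0 passed the adjusted threshold in limma in either reading, and under those run for lists 0 lists did except by the mixed fry p when turned. That p, adjusted over the 4 lists, was 0.0184 for the antenna genes (0.0169 to 0.131 with each array left out) and 0.0184 for tetrapyrrole synthesis (0.0156 to 0.131). The cold and abscisic acid list passed it without replicate 2 (0.0114) and the photosystem list without replicate 3 (0.0150), so each of the 4 lists passed in some setting and which ones did depended on the arrays. For the lists, the 2 other rules for empty cells and the robust moderation were planned and not run, and single probes, no moderation and the fold threshold were not planned. Signal over background was not used here, so its limit is unknown. The number of features at an unadjusted p under 0.05 was 882 (as deposited) and 678 (turned) when a log2 ratio of at least 1 in size was also asked for, which by construction leaves fewer. Leaving out each array in turn gave 1304 to 1827 as deposited and 1316 (without replicate 2) to 2095 (without replicate 4) turned.

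No gene below passed the threshold over all features, and the cause of each change of sign was not tested, apart from the turning itself. As deposited, IAA29 was at -0.1893 with a dye term. On the arrays with the mutant in Cy3 alone, PSAE-1 was at 0.05892, LYC at -0.09547 and SIR at 0.01319, and with the mutant in Cy5 alone LHCB4.3 was at 0.04256 and EXPB3 at -0.2151. With each array left out in turn, PSAE-1 ranged from -0.4995 to 0.1056, LYC from -0.1412 to 0.4501, IAA29 from -0.5677 to 1.466, EXPB3 from -0.0468 to 0.3507, KIN2 from -0.824 to 0.06595, ATHSP22.0 from -0.8622 to 0.1835 and AT2G28390 from -0.4653 to 0.2025. With replicates 1 and 2 turned instead, AT5G18940 was at -0.0394, AT1G80280 at -0.07699, IVD at -0.01006, AT4G19006 at -0.6993, LHCB4.3 at 0.1875, IAA29 at -1.592, EXPB3 at -0.3349, KIN2 at 0.2091 and THI2.1 at 0.3462. The genes named from the turned ratios had, as deposited, -0.3935 (LEA18), -0.07907 (AT5G64100), -0.1182 (AT2G16005), -0.2047 (AT1G04560), -0.2272 (AT3G01190), 0.1963 (AT3G49960), 0.3305 (tny), 0.4187 (AT1G76600), 0.1792 (AT1G24530) and 0.1749 (AT3G07350). Of the remaining values under alternatives, 501 of single genes kept their sign and 155 counts stayed within 1.5 times. These totals do not measure stability. Most of the counts compare 0 with 0, and several settings, such as the variance moderation, leave a mean unchanged by construction. Genes named for having 4 values of 1 sign could not change sign when arrays were left out. A kept sign does not mean a kept size, as in GI (-0.0056) and SIR (-0.0068) without replicate 3, LHCB4.3 (-0.0037) without replicate 2 and PYK10 (0.00038) without replicate 4.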

Other observations

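The tests in this part on sign patterns, families, neighbouring probes, named genes, probe pairs and peroxidases were chosen after the results they bear on had been seen, the bounds of the one on named genes were rewritten after its values were seen, and the running median test was written before its result was known. Further class III peroxidase genes, enzymes of cell wall cross-linking and peroxide turnover, were present among the named genes. Of 19 measured on all 4 arrays, 9 were positive and 10 negative with replicates 1 and 2 turned, and none passed the adjusted threshold in limma. AT5G64120 had a turned log2 ratio of -1.66 ± 1.14, AT2G37130 -0.85 ± 0.33, AT4G36430 0.69 ± 0.40, AT3G28200 -0.63 ± 0.50 and AT5G17820 0.47 ± 0.17 (SD, n = 4 each), each with 1 sign on all 4 arrays. AT2G18980 and PRXR1 had -0.070 ± 0.11 and -0.011 ± 0.18 (SD, n = 4 each). These genes were named after their values were seen.

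Symbol families gave no call. With camera, the glycosyltransferases (UGT, 7 genes on all 4 arrays), the ubiquitin proteases (UBP, 5 genes) and the beta-glucosidases (BGLU, 3 genes) had adjusted p-values of 0.405, 0.433 and 0.591 as deposited and of 0.928 for each when turned. The lower family size was chosen after seeing the data.

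The first pattern is the large ratios of 1 sign on all 4 arrays. It was one-sided, with 104 of the 107 negative. The same-dye pairs alone would give 13.9 negative and 1.01 positive ones, also mostly negative. That reckoning gives every feature the same chance of a large ratio. Large features that turned with the dyes also exceeded it (30 positive against 2.14 and 20 negative against 6.54, after turning). The excess therefore cannot show a relation between the dye orientations, because features that vary more than others would raise all of these counts. A slow trend along the probe order was argued against as the whole source of the large negative ratios. After a running median over 51 neighbouring probes was subtracted, 74 of the 104 stayed large and negative. Of 51 large probes that turned with the dyes, 49 stayed, so the subtraction removed a larger share of the large negative ones. The 74 is above the 52 set as the bound (71.2%, exact 95% interval 61.5% to 79.6%). The interval takes the probes as independent, and their clustering makes it likely too narrow. Neighbouring probes were nevertheless alike in this part (r = 0.270, 95% bootstrap interval 0.242 to 0.297, and 0.199 after the running median) and far less so in the part that turns with the dyes (r = 0.033, 0.014 to 0.054), and 20 of the 104 had a large negative neighbour, against 0.945 in random sets. A genotype difference in a table already turned stays open. In limma, 4.83% of named genes and 7.78% of other features were at an unadjusted p under 0.05. The difference was -2.95 percentage points (95% bootstrap interval over 48 blocks of probes, -3.92 to -1.98). It goes against that explanation only if named genes should change at least as often as other features, which was not tested. The interval of the first share (3.86% to 5.76%) includes 5%. Because same-dye arrays were alike, 5% is not the share to be had without a difference, so this settles nothing. These shares cover all tested features, not the large ratios alone. Of the 107 large ones, 4 were among the 1203 named genes with all 4 values, no clear difference from other features (Fisher's exact test, p = 0.191).

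The second pattern is the ratios that turn their sign with the dyes. Here 8.63% of named genes and 8.80% of other features were at an unadjusted p under 0.05 in limma. One hypothesis is a genotype difference in a table of channel ratios, and a probe-specific dye bias in a table already turned cannot be told apart from it. Over 17 genes with 2 probes the turning part agreed between probes on values (intraclass r = 0.455, one-sided permutation p = 0.0188) but not on ranks (0.118, permutation p = 0.266). The part that kept its sign did not agree (-0.069, permutation p = 0.591), and 8 of the 17 pairs share an accession and may be the same sequence. The pairs include AT3G49960, named above for its small p with similar means of its probes. Agreement without that gene was not tested. Of the 8 sign patterns of the 4 arrays, this one gave the most features at an unadjusted p under 0.05 in limma (1 of 8 as large, 2122, highest other 1829). The ratios as deposited came next (2 of 8 as large, 1829, highest other 2122). Both patterns keep same-dye arrays together, whose likeness by itself raises such counts. The other patterns gave 430 to 1353, and 8 patterns are too few for a share under 0.05.

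The third pattern is the size of the turning ratios of the peroxidases. Their mean size was 0.560 over 19 genes, above 99.9% of 10000 random sets of named genes (one-sided permutation p = 0.00080), whereas with the ratios as deposited it was 0.166, above 3.57% of such sets. The 5 members seen before the list was written carry this: without them the mean size of the other 14 was 0.295 and the permutation p was 0.351. A wider peroxidase response to genotype may therefore not be read from these arrays, and dye bias or cross-hybridisation between paralogs remains open for it.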
